A study of Homo sapiens with 4 samples.

How the data were processed

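RNA was measured in 4 libraries of the hepatocellular carcinoma line Huh7, 2 from cells with a stable short hairpin RNA knockdown of LINC00998 and 2 from cells with a control hairpin, per the labels. Total RNA was made into libraries with a stranded total RNA kit, per the labels' protocols. The labels name the samples by group and number, and the count table numbers its control columns 1 and 3, so the control columns were assigned to the control group and are called here control libraries 1 and 3. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

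The authors deposited a table of read counts per gene, whole numbers that were not normalized. They also deposited FPKM values, fragment counts normalized for gene length and depth, for the same columns. The authors' comparison table gives a log2 fold change of knockdown over control with a p-value and an adjusted p-value per gene, and its file name, one of the deposited labels, names DESeq. A shorter table holds the genes with a p-value under 0.05 and a fold of over 2, and the authors' deposited summary holds other values, namely the numbers of genes higher, lower and in total in that list. Trimmomatic 0.36, HISAT2 2.0.5, Cufflinks 2.2.1 and HTSeq 0.9.1 were used, per the submitters' processing notes, which give no roles or order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed. The count table holds 19974 genes, nearly all protein-coding per the biotype column of the authors' comparison table, and no mitochondrially encoded or small noncoding RNA was analysed here. The targeted transcript LINC00998, also named SMIM30, was not analysed here.

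Total counts were 19086204 in control library 1, 18871220 in control library 3, 18833952 in knockdown library 1 and 18520030 in knockdown library 2. At these depths a count of 0 allows a level of up to 0.157 to 0.162 CPM, taking 3 counts as the limit, and this covers counting error only. The libraries of a group differed by more than sampling noise (chi-square per degree of freedom 15.7 for the controls and 15.6 for the knockdown), and each library was fitted as its own replicate.

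The main comparison was fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3, with Benjamini-Hochberg adjustment over the 12210 genes kept and a threshold of 0.05. CPM in the text are counts divided by the library total, given as mean ± SD. Gene lists were tested with camera in limma 3.58.1 with the correlation preset at 0.01, adjusted over the 29 lists with at least 5 tested members. Camera with an estimated correlation and fry were the alternatives. Both were run on the main fit only, so every camera p-value after the GC and length correction described below rests on the preset. The design, the alternatives, the 35 gene lists and the rule for named genes were fixed before the data were examined. That rule names the 12 largest rises and the 12 largest falls among genes past the threshold, at least 2-fold, with all knockdown libraries on one side of all control libraries and a mean of at least 5 CPM in the higher group. It adds up to 4 members of each list past the threshold with at least 1 CPM. Some genes that the rule names are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

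Transcript GC content and length were those of the longest protein-coding GENCODE v29 transcript of each gene symbol. That transcript need not be the one these cells express. Of the 19974 genes, 18467 matched by symbol and 517 by an older symbol, and 98.7% of tested genes had a value. An added alternative, chosen after seeing the data, removed each library's smooth trend of log2 CPM with GC content and length (natural splines with 5 degrees of freedom, fitted on genes with a mean count of at least 50) and repeated the edgeR test with these trends as offsets. Neighbouring genes were taken from the RefSeq gene table of GRCh38.p14 for their order only. Pathway names came from the annotation column of the authors' comparison table. Other scalings (RLE, upper quartile, library totals alone), filters, DESeq2 1.42.0, robust estimation, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM values, removal of the 20 most abundant genes and removal of each library in turn were the other alternatives. Random gene sets and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

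The edgeR procedure was tested on simulated counts drawn from the means and totals of these 4 libraries, with 200 seeded genes changed and a biological coefficient of variation of 0.1. With no GC trend, 169 of 12123 genes were called, 12 of them false, and 98.5% of genes seeded at a log2 change of 1 were recovered against 37.3% at 0.5. With a GC trend added to the libraries, 4382 of 12139 genes were called without the correction, 4206 of them false. With it, 151 of 11985 were called, 2 of them false, and 27.3% of genes seeded at 0.5 were recovered. The added trend ran in opposite directions in controls and knockdown and was of the kind the correction removes. Seeded genes were picked without regard to GC content. The simulation therefore cannot tell how real changes that follow GC content would fare.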

Results

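Gene expression was measured by RNA sequencing in 2 libraries from Huh7 cells stably expressing a short hairpin RNA against LINC00998 and 2 libraries from cells with a control hairpin. Huh7 is a cell line derived from a human hepatocellular carcinoma, and LINC00998 is a transcript annotated as a long noncoding RNA that also encodes the small membrane protein SMIM30. The series asks which genes differ between knockdown and control cells. Totals ranged from 18520030 to 19086204 counts per library, and 14144 to 14365 genes had at least 1 count in a library. The targeted transcript was not analysed here, so its level does not check the labels.

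Many genes of differentiated hepatocytes were at or near 0 in both groups. Of 25 secreted plasma protein genes, 23 had at most 10 counts in every library and 11 had no count in any. Among members named after their values were seen, ALB (albumin) and APOB (apolipoprotein B) had 0 counts in all 4 libraries, which allows at most 0.162 CPM, and AFP (alpha-fetoprotein) had at most 2. The other 2 were APOE (apolipoprotein E), named after its values were seen, with 5 to 11 counts, and VTN (vitronectin), at 426 ± 14.6 CPM in the controls and 372 ± 1.31 CPM in the knockdown (SD, n = 2 each). Of 21 liver transcription factors 11 stayed at or below 10 counts in every library, and FOXA2 and PROX1, also named after their values were seen, had 0. At or below that level were 25 of 30 acute phase, complement and coagulation genes, 18 of 22 bile acid and transporter genes, 21 of 30 xenobiotic metabolism genes and 12 of 23 gluconeogenesis, urea cycle and amino acid catabolism genes. The keratin genes KRT8 and KRT7 were abundant, with control means of 3817 ± 574 and 3112 ± 314 CPM (SD, n = 2).

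The comparison of knockdown with control cells asks which genes respond to the loss of the transcript. The knockdown libraries had higher levels of the immediate early transcription factor genes EGR1 and FOS and of the interferon-induced genes OAS2 and IFI44L. They had lower levels of the hypoxia-induced carbonic anhydrase gene CA9, the actin crosslinker gene ACTN4 and most members of fixed lists of cytosolic ribosomal protein genes and of glycolysis and hypoxia genes. ACTN4 lies near another strongly changed gene, so part of its fall may come from how reads were assigned. EGR1 differed between knockdown libraries 1 and 2, at 23.4 and 5.56 CPM. Its log2 fold change was 3.13 with all libraries and 1.74 without knockdown library 1. FOS was at 101 ± 30.4 CPM in the knockdown and 22.0 ± 1.37 in the controls (SD, n = 2 each), a log2 fold change of 2.07 ± 0.21 (SE, edgeR adjusted p = 0.00401). CA9 was at 6.43 ± 3.97 CPM against 44.7 ± 18.3, a log2 fold change of -2.90 ± 0.42 (SE, edgeR adjusted p = 0.00401).

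In all, 6493 of 12210 tested genes passed an edgeR adjusted p of 0.05, 3299 higher and 3194 lower in the knockdown, and 668 of them differed at least 2-fold (363 higher, 305 lower). The median size of the called changes was 0.63 on the log2 scale. With library totals as the only scaling, 62.7% of calls were higher against 50.8% with TMM, and the median log2 fold change of all genes moved from 0.02 to 0.14. The change followed the GC content of the transcript. Across genes, which are not independent replicates, the Spearman correlation of GC content with log2 fold change was -0.735, and that of transcript length was 0.35. The 1205 genes with the lowest GC content had a median log2 fold change of 0.59 and the 1205 with the highest -0.59. Called genes higher in the knockdown had a median GC content of 41.6%, and called lower genes 58.8%. With each library's GC and length trend removed, an alternative chosen after seeing the data, 2456 genes were called (1272 higher, 1184 lower), 1509 of them in both fits in the same direction, and 240 differed at least 2-fold. Without control library 1 the count was 3184.

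**Figure D1:**
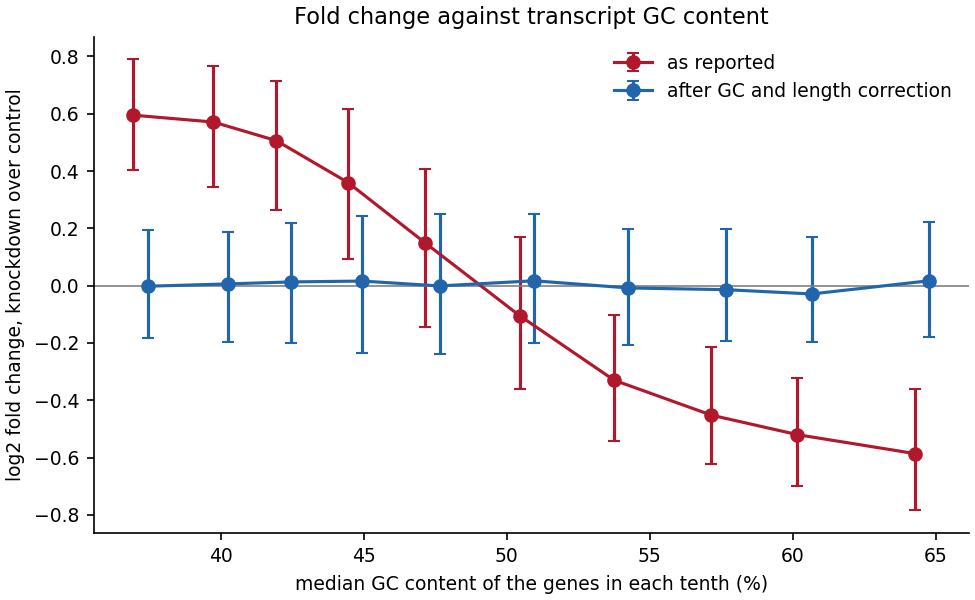
Median log2 fold change (knockdown over control, vertical axis) of tested genes in 10 groups of rising transcript GC content (horizontal axis, %), with bars from the lower to the upper quartile; red is the comparison as reported and blue the one after GC and length correction, the points being shifted sideways for clarity. The red medians run from 0.59 at the lowest GC content to -0.59 at the highest, and the blue medians lie between -0.03 and 0.02.

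The authors' deposited table lists 217 genes at an unadjusted p-value under 0.05 and over 2-fold, 121 higher and 96 lower. Of these, 212 were called in the same direction by edgeR and 188 of the 214 with a GC value after the GC and length correction. The authors' deposited table has 5740 genes with an adjusted p under 0.05, 2913 higher and 2827 lower. Across tested genes, its log2 fold changes and those of edgeR had a Pearson correlation of 0.939. Several of the largest edgeR changes were smaller in the authors' deposited table and not past an adjusted p of 0.05 there: EGR1 (0.54, adjusted p = 0.088, against 3.13), ECH1 (-0.36, 0.156, against -5.03), EEF1D (-0.64, 0.0722, against -2.20) and IGFBP3 (-0.64, 0.0836, against -1.94). CA9 was at -0.87 there (adjusted p = 0.0141) against -2.90. XAF1, with 1 and 0 counts in the controls and 24 and 40 in the knockdown, was at 0.999 there against 5.60. That is smaller than its counts give. The authors' log2 fold changes may therefore be shrunken estimates, which was not tested, and their sizes are not like for like with those of edgeR.

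Among the 12 largest rises, the splicing regulator gene HNRNPL changed most, from 5.71 ± 1.48 CPM in the controls to 75.4 ± 39.2 in the knockdown (SD, n = 2 each; log2 fold change 3.60 ± 0.40 SE, edgeR adjusted p = 0.00401). EGR1 followed with a log2 fold change of 3.13 ± 0.71 (edgeR adjusted p = 0.011). Its knockdown libraries were at 23.4 and 5.56 CPM, and the value was 1.74 without knockdown library 1 and 2.65 without control library 1, no longer past the threshold (edgeR adjusted p = 0.08). The remaining 10 were FAM189B (2.42), ANKRD1 (2.17), FOS (2.07), OAS2 (2.02), IFI44L (1.92), the RNA-binding protein gene HNRNPR (1.86), the endoplasmic reticulum chaperone gene HYOU1 (1.78), the HSP70 gene HSPA1B (1.64), the polarity gene PARD6B (1.63) and GOLGA8B (1.63). HNRNPR missed the threshold after the GC and length correction (log2 fold change 1.35, edgeR adjusted p = 0.202) and was at 0.57 without knockdown library 1, 2.12 without control library 1 and 1.64 without control library 3, past the threshold in none of these. PARD6B was at 1.03 after the GC and length correction. Reads of HSPA1B and GOLGA8B can be shared with near-identical copies, so their values are uncertain. HNRNPL and HYOU1 each lie within 100 kb of another strongly changed gene. CLK2, near FAM189B and chosen after its values were seen, had 5 and 224 counts in knockdown libraries 1 and 2. Reads assigned differently between copies of a region may underlie part of the changes of HNRNPL, HYOU1 and FAM189B.

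Of the 12 largest falls, ACTN4 had the smallest p, going from 96.4 ± 13.3 CPM to 6.32 ± 0.23 (SD, n = 2 each; log2 fold change -4.05 ± 0.16 SE, edgeR adjusted p = 4.14e-04). ACTN4 and ECH1 lie within 100 kb of each other, and reads assigned differently between copies of a region may underlie part of their changes. The proteasome subunit gene PSMB3 went from 62.9 ± 8.18 to 7.04 ± 3.78 CPM, a log2 fold change of -3.28 ± 0.32 (edgeR adjusted p = 0.00401). PCGF2, near PSMB3 and chosen after its values were seen, had 8 and 330 counts in knockdown libraries 1 and 2. How reads were assigned may therefore underlie part of the fall of PSMB3. The others without dependence on 1 control library were CA9 (-2.90), TMEM238 (-2.60), LRRC26 (-2.03) and TMEM121 (-1.89). The last 3 were at -1.64, -1.08 and -1.08 after the GC and length correction. The fatty acid oxidation gene ECH1 (-5.03) rested on control library 3, and without that library its log2 fold change was -1.84. The elongation factor gene EEF1D (-2.20) and the insulin-like growth factor binding protein gene IGFBP3 (-1.94) were at -1.37 and -1.01 without it. NAPRT, near EEF1D and chosen after its values were seen, had 125 and 6 counts in knockdown libraries 1 and 2. The limit on read assignment therefore holds for EEF1D too. LY6E (-2.21) and NMRAL1 (-1.95) were at -0.23 and -0.74 without control library 1 and no longer past the threshold (edgeR adjusted p = 0.662 and 0.212). They were at -1.48 and -1.31 after the GC and length correction, not past the threshold (edgeR adjusted p = 0.19 and 0.128).

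**Figure D2:**
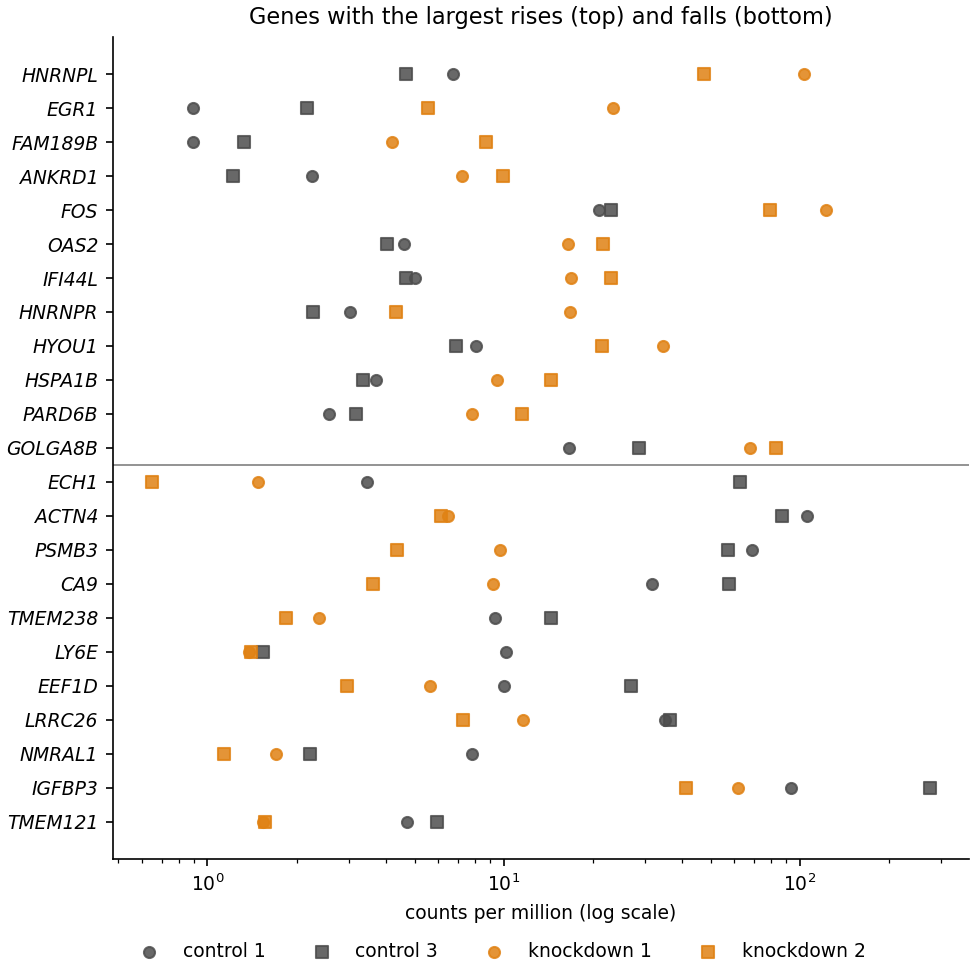
CPM (horizontal axis, log scale) of the 12 genes with the largest rises and 11 of those with the largest falls in each of the 4 libraries (grey control, orange knockdown, circles library 1, squares control library 3 and knockdown library 2). ACTN4 stands at 106 and 87.0 CPM in the controls against 6.48 and 6.16 in the knockdown.

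Most of the cytosolic ribosomal protein, glycolysis and hypoxia, and oxidative phosphorylation genes tested were lower in the knockdown. Of 29 cytosolic ribosomal protein genes 24 fell and none rose, the same when adjusted over the list alone, with a median log2 fold change of -0.61 (camera adjusted p = 7.98e-10; adjusted p = 0.83 with an estimated correlation). RPS2 fell from 2426 ± 49.0 to 1309 ± 178 CPM and RPLP0 from 3877 ± 108 to 2270 ± 187 (SD, n = 2 each), and RPL13 and RPS18 fell by 0.95 and 0.92 on the log2 scale. RPS18, whose reads can be shared with copies, was at -0.69 without control library 1 and not past the threshold (edgeR adjusted p = 0.0526). With the GC and length correction RPS2 was at -0.29 (-1.01 as reported), RPLP0 at -0.37 (-0.89), RPS18 at -0.41 and RPL13 at -0.65, all past the threshold. The transcript taken for RPL13 was 4498 bases long, against 993 for RPS2 and 1344 for RPLP0. The corrected value of RPL13 depends on that choice of transcript. The median GC content of this list was 51.1%, and after the GC and length correction 18 members were lower, none was higher, and the median was -0.36 (camera adjusted p = 2.56e-12). Of 28 glycolysis and hypoxia genes 18 fell and 1, KDM3A, named after its value was seen, rose (19 and 1 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 6.38e-06; adjusted p = 0.83 with an estimated correlation). CA9, the stress-responsive gene NDRG1 (-1.86 ± 0.29 SE), the aldolase gene ALDOC (-1.17 ± 0.13 SE) and PFKFB4 (-0.93 ± 0.20 SE), which makes the glycolytic regulator fructose 2,6-bisphosphate, led these falls. ALDOC was at -0.70 after the GC and length correction. The controls already differed for 3 of these 4 genes. In control libraries 1 and 3 CA9 was at 31.7 and 57.6 CPM, NDRG1 at 366 and 724 and PFKFB4 at 24.7 and 39.3. ALDOC was at 69.7 and 73.7 CPM there. PFKFB4 was at -0.60 without control library 3 and at -0.59 after the correction (edgeR adjusted p = 0.0841). Their median GC content was 55.2%, and after the correction 12 were lower, 2 were higher and the median was -0.29 (camera adjusted p = 3.87e-05). In the authors' wider Glycolysis / Gluconeogenesis pathway, tested after the data were seen, 19 of 44 genes fell and 8 rose (camera adjusted p = 0.172), and 10 were lower and 3 higher after the correction (camera adjusted p = 0.636). Of 28 nuclear-encoded oxidative phosphorylation genes 15 fell and 2 rose, the same when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.00792; adjusted p = 0.83 with an estimated correlation). Among the falls were UQCRC1 (-0.84), NDUFB8 (-0.71), COX5B (-0.66) and COX4I1 (-0.63), of which NDUFB8 (-0.13) and COX5B (-0.18) missed the threshold after the correction (edgeR adjusted p = 0.24 and 0.113) and UQCRC1 and COX4I1 were at -0.32 and -0.37. With a median GC content of 47.8%, the list had 12 lower members, none higher and a median of -0.18 after the correction (camera adjusted p = 2.17e-04). Without knockdown library 2 its camera adjusted p was 0.252.

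Of 23 ATF4 and amino acid stress genes 13 fell and 1 rose, the same when adjusted over the list alone, with a median of -0.79 (camera adjusted p = 7.28e-04; adjusted p = 0.83 with an estimated correlation). The glutathione-degrading enzyme gene CHAC1 (-1.87 ± 0.51 SE), the mTORC1 inhibitor genes DDIT4 (-1.11 ± 0.22 SE) and SESN2 (-1.02 ± 0.23 SE) and the pseudokinase gene TRIB3 (-0.98 ± 0.17 SE) were the largest falls named by the rule (n = 2 libraries per group). After the GC and length correction these 4 were at -1.28, -0.60, -0.62 and -0.49, in the same direction but not past the threshold (edgeR adjusted p = 0.102 to 0.123). The rise was in SLC7A11, the cystine transporter gene, named after its value was seen (0.97). The median GC content was 50.8%, and after the GC and length correction 9 were lower, none was higher and the median was -0.50 (camera adjusted p = 3.15e-05). Without control library 3 the camera adjusted p was 0.0718, CHAC1 was at -0.80 (edgeR adjusted p = 0.078) and DDIT4 and SESN2 were at -0.70 and -0.61.

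Of 23 tested interferon-stimulated genes 13 rose and 3 fell, the same when adjusted over the list alone, with a median log2 fold change of 0.60 (camera adjusted p = 0.00792; adjusted p = 0.83 with an estimated correlation). OAS2 rose from 4.32 ± 0.41 to 19.1 ± 3.67 CPM and IFI44L from 4.85 ± 0.26 to 19.9 ± 4.29 (SD, n = 2 each), IFI44L being at 1.27 on the log2 scale after the correction against 1.92 as reported. XAF1 had 1 and 0 counts in the controls and 24 and 40 in the knockdown (log2 fold change 5.60 ± 0.77 SE, edgeR adjusted p = 0.00401). The ratio of CPM was 65.0 with an exact 95% counting interval from 11.3 to 2610. That interval uses counts summed over each group, so it covers counting error only and leaves out the spread between libraries. MX2 had 9 and 1 counts against 26 and 22 (edgeR adjusted p = 0.0309). Its log2 fold change was 2.14 with all libraries and 4.35 without control library 1. Without control library 3 it was 1.28, and its call was lost. The falls, named after their values were seen, were ISG15 (-0.60, and 0.20 after the GC and length correction), OASL (-0.60) and OAS1 (-0.35). The median GC content of the list was 48.2%, and after the correction 11 were higher, 2 were lower and the median was 0.23 (camera adjusted p = 3.87e-05). The list's camera adjusted p was 0.151 without control library 3 and 0.0527 by limma on log2(FPKM + 0.1), and without knockdown library 2 its median was 0.37.

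**Figure D3:**
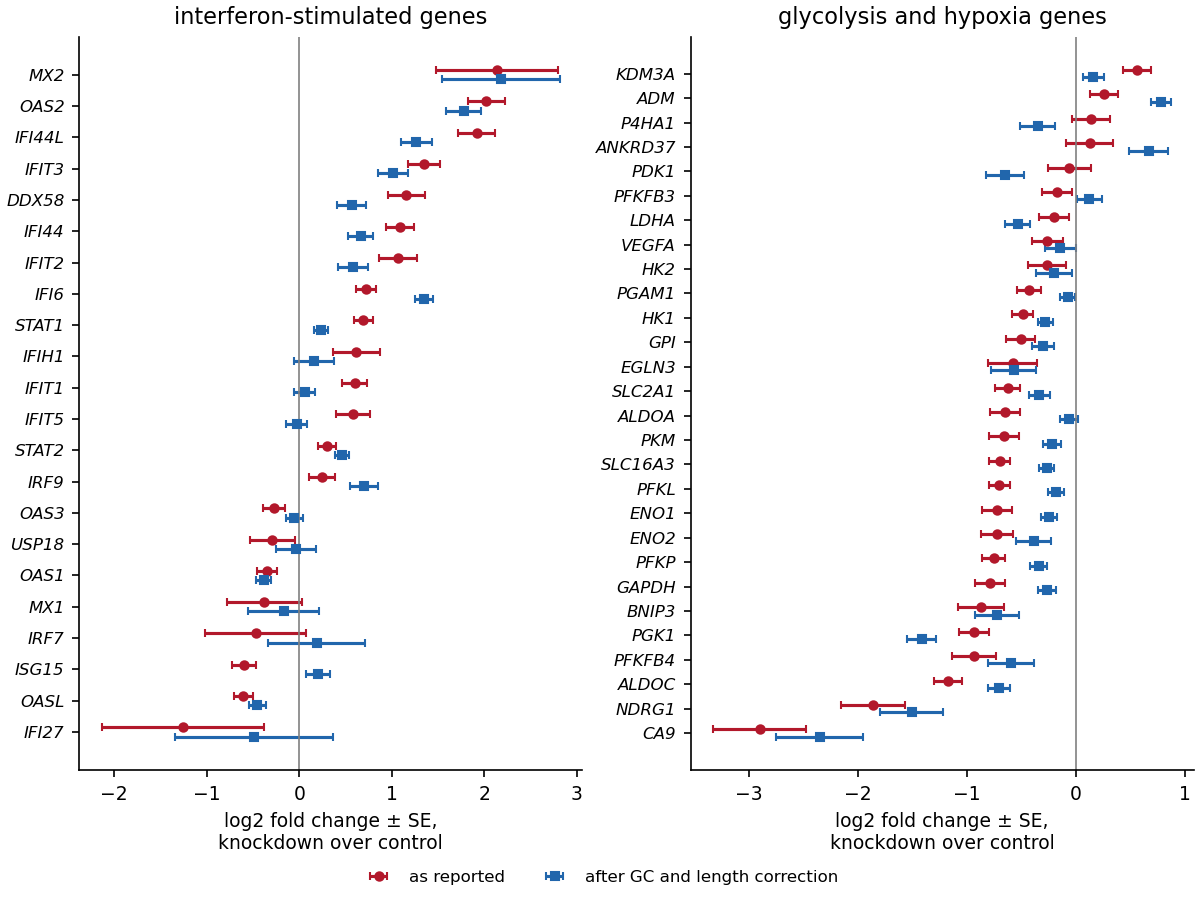
Log2 fold change ± SE (horizontal axes, knockdown over control, n = 2 libraries per group) of each tested interferon-stimulated gene except XAF1 (left) and each glycolysis and hypoxia gene (right), red as reported and blue after GC and length correction. OAS2 stands at 2.02 as reported and 1.78 after correction, and CA9 at -2.90 and -2.35.

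A further 3 lists missed the camera threshold as reported and passed it after the GC and length correction. As reported, their adjusted p with an estimated correlation was 0.83 for the unfolded protein response and mesenchymal lists and 0.833 for the YAP/TEAD list. Of 22 unfolded protein response genes 11 rose and 3 fell (median 0.25, camera adjusted p = 0.0746), the same when adjusted over the list alone. The largest rises were HYOU1 (1.78), DNAJB9 (1.05), DNAJC3 (0.98) and SEL1L (0.81), and the last 3 missed the threshold after the correction (0.53, 0.36 and 0.16; edgeR adjusted p = 0.111, 0.0648 and 0.206). HYOU1 lies near another strongly changed gene, so part of its rise may come from how reads were assigned. After the correction 6 were higher and none lower (median 0.26, camera adjusted p = 0.00223). Their median GC content was 48.0%. Of 16 YAP/TEAD target genes 6 rose and 2 fell (median 0.10, camera adjusted p = 0.452), the same adjusted over the list alone. The largest were ANKRD1 (2.17), TGFB2 (1.06), F3 (1.02) and CTGF (0.89), of which TGFB2 missed the threshold after the correction (0.43, edgeR adjusted p = 0.175). After the correction 7 were higher and none lower (median 0.31, camera adjusted p = 0.0113) at a median GC content of 51.6%. Without knockdown library 1 CTGF was at 0.46 and no longer past the threshold (edgeR adjusted p = 0.217), nor was it without control library 1 (1.21) or 3 (0.63). Without control library 1 DNAJB9 (0.93), SEL1L (0.69) and TGFB2 (1.04) missed the threshold, and DNAJB9 was at 0.62 without knockdown library 2. Of 23 mesenchymal and migration genes 12 fell and 4 rose (13 and 5 adjusted over the list alone; median -0.50, camera adjusted p = 0.0853). After the correction 4 were lower and none higher (median -0.18, camera adjusted p = 0.0208) at a median GC content of 53.2%. The lysyl oxidase gene LOX (-1.75, and -0.76 without control library 3), the integrin gene ITGA5 (-1.21), TGFB1 (-1.18) and MMP2 (-1.09) were its largest changes. MMP2 (-0.98 to -1.19) missed the threshold without any 1 of the 4 libraries and, after the correction, with all 4 (-0.75, edgeR adjusted p = 0.176). F3 and TGFB1 were at 0.68 and -0.65 after the correction. Over the 16 alternatives the camera adjusted p ran from 0.00223 to 0.245 for the unfolded protein response, 0.0113 to 0.773 for the YAP/TEAD and 5.72e-04 to 0.401 for the mesenchymal list.

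The other lists did not pass camera as a whole as reported or after the correction. In other settings the G2/M list passed with library totals alone (camera adjusted p = 0.0291), with DESeq2 (0.0376) and without control library 1 (0.0078) or knockdown library 1 (0.00611), its range over 16 settings being 0.00611 to 0.447. The heat shock list passed without control library 1 (camera adjusted p = 0.0251). Among MAPK/ERK target genes, EGR1 and FOS rose with 1 more of 21 and 5 fell (2 and 5 adjusted over the list alone), including IER2 (-0.65) and ETV4 (-0.64). The list's camera adjusted p was 0.771 at a median GC content of 52.6%. With the correction it had 3 higher members and none lower, IER2 (-0.17) and ETV4 (-0.13) missing the threshold. In the receptor tyrosine kinase, SRC and MAPK cascade list 11 of 26 fell and 5 rose, with MAPK3 (-0.94), FGFR1 (-0.92) and ERBB3 (-0.85) lower and NRAS (0.78) higher, at a median GC content of 51.5%. With the correction 4 were lower and 1 higher, MAPK3 was at -0.43 and FGFR1 at -0.64, and NRAS (0.17) and ERBB3 (-0.73, edgeR adjusted p = 0.0629) missed the threshold. Of 24 G2/M and mitosis genes 9 rose and 3 fell (median 0.37, camera adjusted p = 0.0681). The largest were NUSAP1 (0.85), KIF11 (0.81), TOP2A (0.79) and KIF23 (0.75). The median GC content was 43.8%, and 5 were higher and none lower after the correction, KIF11 (0.17), TOP2A (0.14) and KIF23 (0.25) missing the threshold and NUSAP1 being at 0.45. TOP2A and KIF11 were at 0.43 (edgeR adjusted p = 0.0528) and 0.47 without knockdown library 2, and at 0.71 and 0.74 and not past the threshold without control library 1. Of 27 G1/S and DNA replication genes 10 rose and 6 fell (10 and 7 adjusted over the list alone), E2F8 (1.09), RFC3 (0.91) and MCM10 (0.85) among the rises. E2F2 (1.94) was at 0.57 without knockdown library 2, missing the threshold there and without control library 1 (1.91) or 3 (1.97) (median GC content 49.1%), and the list had 6 higher and 3 lower members after the correction, with RFC3 at 0.41 and MCM10 at 0.37. Of 21 p53 target genes 8 rose and 5 fell (8 and 7 adjusted over the list alone), led by RRM2B (1.21), ZMAT3 (1.20), MDM2 (1.13) and TP53INP1 (0.92), whose GC contents were 36.4% to 41.9% against a list median of 50.3%. With the correction 4 were higher and none lower, the values of these being 0.60, 0.58, 0.58 and 0.33, and TP53INP1 missed the threshold (edgeR adjusted p = 0.383). TP53INP1 missed the threshold without control library 1 (0.73) or knockdown library 1 (0.69), and ERBB3 without control library 3 (-0.68) or knockdown library 1 (-0.74). Heat shock genes had 6 rises and 2 falls of 15, with HSPA1B (1.64) and HSPH1 (0.96) higher and HSPB1 (-0.96) lower, at a median GC content of 50.2%. Corrected, 2 were higher and none lower, and HSPH1 (0.33) and HSPB1 (-0.18) missed the threshold. Of 18 histone genes 1 fell, HIST1H1C, by 0.56 on the log2 scale (median GC content 49.4%), and without control library 1 it was at -0.42 and not past the threshold. After the correction it was at 0.14 and not past it either, and 2 other histone genes were higher.

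Lipid genes changed both ways as reported, and fewer were called after the GC and length correction. Of 24 cholesterol synthesis and uptake genes 6 rose and 8 fell (6 and 9 adjusted over the list alone), HMGCS1 (1.11), STARD4 (1.09) and MSMO1 (0.78) upward and LSS (-0.86, and -0.43 without control library 1) downward, at a median GC content of 52%. With the correction 2 were higher and none lower, HMGCS1 (0.53, edgeR adjusted p = 0.0576), MSMO1 (0.27) and LSS (-0.51) missing the threshold and STARD4 being at 0.50. Of 19 fatty acid synthesis and storage genes 4 rose and 6 fell, with LPIN1 (0.99) and ELOVL6 (0.82) higher and ACACA (-1.60), the acetyl-CoA carboxylase gene, and DGAT2 (-0.83) lower (median GC content 52.2%). Corrected, 1 was higher and 1 lower, and ELOVL6 (0.23) and DGAT2 (-0.42) missed the threshold. AATF, near ACACA and chosen after its values were seen, had 364 and 19 counts in control libraries 1 and 3. It had 27 and 217 in knockdown libraries 1 and 2. How reads were assigned may therefore underlie part of the fall of ACACA. Of 19 fatty acid oxidation and ketogenesis genes 4 rose and 6 fell (4 and 7 adjusted over the list alone), with ANGPTL4 at -1.59, ACADS at -0.87, ACAA1 at -0.66 and PPARGC1A at 0.95 (median GC content 49.6%). In the corrected fit 3 were lower and none higher, and ACADS (-0.23), ACAA1 (-0.15) and PPARGC1A (0.35) missed the threshold, ANGPTL4 being at -0.99. Without control library 1 LSS, DGAT2 (-0.82), ELOVL6 (0.68) and PPARGC1A (0.71) missed the threshold. In the gluconeogenesis, urea cycle and amino acid catabolism list 2 of 11 rose and 5 fell, PCK2 (-1.09) and ASL (-0.84) among the falls, at a median GC content of 57.4%. Corrected values gave 1 higher and 2 lower, with PCK2 (-0.59, edgeR adjusted p = 0.0651) missing the threshold and ASL at -0.34. Of 19 endoplasmic reticulum calcium genes 5 rose and 6 fell (9 and 6 adjusted over the list alone), ATP2A3 (-1.33), ORAI3 (-0.95), ORAI2 (-0.78) and STIM1 (-0.56) being lower, at a median GC content of 47.1%. The correction left 2 lower and none higher, ORAI3 (-0.46) and STIM1 (-0.25) missing the threshold and ATP2A3 and ORAI2 being at -0.89 and -0.47. That list had a median of 0.26, a mean of -0.03 and a camera direction of down. The median, mean and camera direction also differed in sign for the MAPK/ERK targets (-0.27, 0.11 and down) and the G1/S genes (-0.04, 0.14 and up).

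Of 10 tested liver transcription factors 3 fell and none rose, CEBPB (-1.36), CEBPA (-0.99) and CEBPD (-0.84). Their GC contents were 66.2%, 65.9% and 70.0% (list median 56.2%), and of the 3 CEBPB alone was past the threshold after the correction (-0.69, edgeR adjusted p = 0.00625). In the tested acute phase, complement and coagulation genes 2 of 5 fell, F12 (-1.02) and C3 (-0.33), at a median GC content of 53.2%, and after the correction C3 (-0.03) missed the threshold and F12 was at -0.39. Of the xenobiotic metabolism genes CYP1B1 (0.98) rose and GSTM3 (-0.64) fell, and of the bile acid genes ABCC2 (0.94) rose and SLC27A5 (-0.92) fell, at median GC contents of 45.8% and 50.4%. After the correction SLC27A5 (-0.36) missed the threshold, and CYP1B1, GSTM3 and ABCC2 were at 0.53, -0.97 and 0.53. Of 18 NF-kappaB and inflammatory genes 2 rose, CCL2 (0.84) and CXCL2 (0.64), and 5 fell, RELB (-0.90) and IL32 (-1.41) among them, at a median GC content of 45.8%. All 4 missed the threshold after the correction (0.61, 0.56, -0.29 and -0.85), when 1 other member was higher and 1 lower. Epithelial junction genes had 1 rise, CLDN1 (0.61), and 4 falls of 13, with CLDN7 (-1.11), TJP3 (-0.70) and KRT8 (-0.60), at a median GC content of 53.4%. No junction gene was past the threshold after the correction, these being at 0.10, -0.58, -0.21 and -0.28. Of 11 Wnt/beta-catenin targets DKK1 (0.67) rose and SP5 (-1.14) fell (median GC content 53.5%), SP5 (-0.48) missing the threshold and DKK1 being at 0.37 after the correction. Of 7 biliary and progenitor markers IGF2BP3 (0.89), PEG10 (0.55) and CD24 (0.54) rose and KRT7 (-0.75) fell (median GC content 49.6%), and with the correction CD24 (0.30) alone was past the threshold, the others being at 0.31, 0.13 and -0.12. Without control library 1 C3 (-0.27), SLC27A5 (-0.76), IL32 (-1.23), CCL2 (1.02), CXCL2 (0.45), CLDN1 (0.42), KRT8 (-0.40), SP5 (-0.99) and PEG10 (0.42) missed the threshold. RELB (-0.54) and CCL2 (0.68) missed it without control library 3, CXCL2 (0.36), IL32 (-1.40) and C3 (-0.27) without knockdown library 1, and CCL2 (0.79), IL32 (-1.41), SP5 (-0.94) and C3 (-0.39) without knockdown library 2.

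Markers of other cell types were mostly at or near 0. At most 10 counts in every library were found for 12 of 15 immune, 9 of 12 endothelial, 5 of 14 fibroblast and stellate and 10 of 15 squamous and other epithelial markers. The 3 tested immune markers fell, CSF1R (-1.76), CD14 (-1.15) and CD68 (-0.89), at 1.02, 0.59 and 18.6 CPM in the knockdown. The endothelial marker ESAM rose (1.26), the fibroblast markers COL1A1 (-0.88) and PDGFRB (-0.59) fell and FAP (0.65) rose, and KRT14 (-1.58) and SFN (-0.60) fell. Median GC contents were 57.3% for the tested immune, 54.5% for the endothelial, 45.3% for the fibroblast and 56.3% for the squamous markers. With the correction CSF1R (-1.42), ESAM (1.77) and COL1A1 (-0.50) were past the threshold, and CD14 (-0.64), CD68 (-0.46), PDGFRB (-0.27), FAP (0.13), KRT14 (edgeR adjusted p = 0.108) and SFN (0.09) were not. Without control library 1 FAP (0.44), PDGFRB (-0.50), CD14 (-1.06), ESAM (1.28) and KRT14 (-1.67) missed the threshold, as did all of these but FAP without control library 3. PDGFRB (-0.38) and ESAM (1.09) missed it without knockdown library 2 and CD14 (-0.81) without knockdown library 1. For the lists named from the receptor tyrosine kinases to these markers, the counts were the same adjusted over the list alone where no second count is given.

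**Figure D4:**
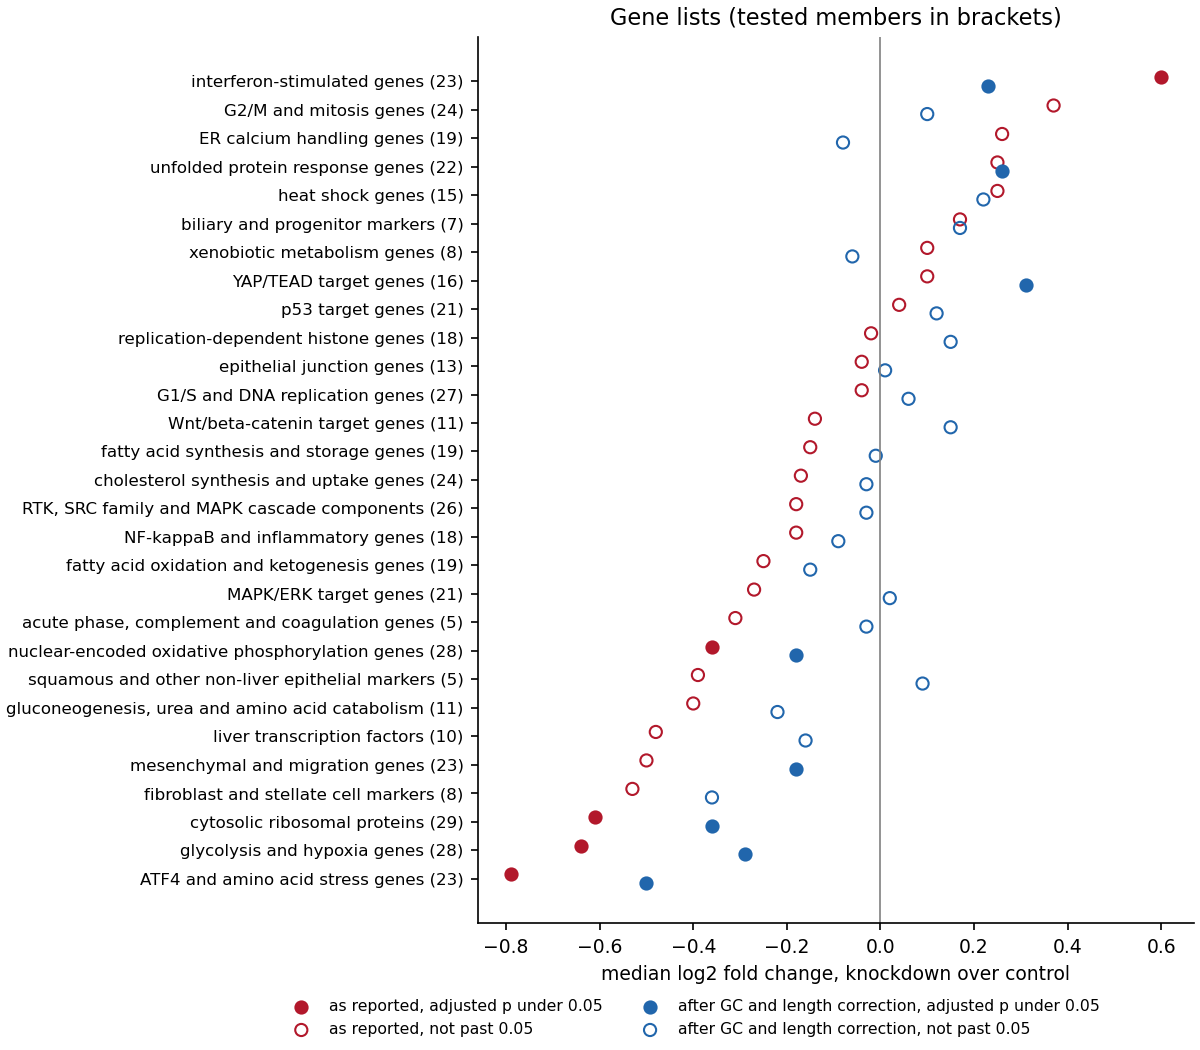
Median log2 fold change (horizontal axis, knockdown over control) of the 29 gene lists tested, with the number of tested members in brackets; red is as reported, blue after GC and length correction, and filled points have a camera adjusted p under 0.05. The medians run from -0.79 for the ATF4 and amino acid stress genes to 0.60 for the interferon-stimulated genes as reported, 5 red and 8 blue points being filled.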

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

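The GC and length correction and the interferon list median were chosen after the data were seen, and the other alternatives here before. No paired analysis was possible because the count columns share only replicate number 1, the controls being numbered 1 and 3 and the knockdown 1 and 2, so the planned block on the replicate number was not run. For the targeted transcript no alternative was run. With RLE or upper-quartile scaling, library totals alone, no filter, a mean count of at least 10, DESeq2, robust estimation or removal of the 20 most abundant genes, each count of genes stayed within 1.5 times the reported one, and 5 to 7 lists passed. On log2(FPKM + 1) limma called 4645 genes, 90 of them at least 2-fold, and 256 at least 2-fold with a pseudocount of 0.1. Without a filter it called 2553 (1298 higher, 1255 lower), 73 of them at least 2-fold, with 15080 genes tested, and the pseudocount shrinks the folds of low genes. The GC and length correction gave 2456 calls (1272 higher, 1184 lower), 240 at least 2-fold and 8 lists, by removing the trend it models. At an unadjusted p under 0.05 and 2-fold DESeq2 called 586 genes, 327 higher and 259 lower, against 217 in the authors' deposited table. The authors' log2 fold changes may be shrunken estimates, which would pass a 2-fold limit less often, and the cause was not tested. With an estimated correlation camera passed 0 lists, 0 of them at an unadjusted p under 0.05, and fry passed 1, the liver transcription factors (adjusted p = 0.0242). The lists that passed as reported had estimates of 0.919 (ribosomal), 0.856 (ATF4), 0.762 (oxidative phosphorylation), 0.359 (glycolysis and hypoxia) and 0.327 (interferon). The preset was 0.01.

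Without each library in turn, which leaves a lone sample assumed to vary like the other group, called genes ranged from 3184 (without control library 1) to 6176, higher ones from 1495 to 3280, lower ones from 1689 to 2896, those at least 2-fold from 454 to 1163 (without knockdown library 1). Lists ranged from 3 (without control library 3) to 9 and the interferon list median from 0.37 to 0.74. Of 126 named genes 87 kept their call and direction in all 4 of these fits, and 44 in all 16 settings. Outside the correction 0 reversed, and with it HIST1H1C, VTN and SFN went from negative values to 0.14, 0.13 and 0.09, none past the threshold. What depth limits was not tested by varying it.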

Other observations

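The tests of library size, of pairs in opposite directions and of all 4 explanations for the hepatocyte genes, the correction itself and the pathway tests were chosen after the result was seen. Over 271 pathways named in the authors' annotation with at least 10 tested genes, 10 passed camera as reported, 9 after the GC and length correction and 8 in both in the same direction. The Ribosome pathway had 74 falls and 2 rises of 128 genes (median log2 fold change -0.45, camera adjusted p = 5.43e-10) and 52 falls and 3 rises after the correction (camera adjusted p = 1.21e-12). Biosynthesis of amino acids had 30 falls and 9 rises of 58 (median -0.45, camera adjusted p = 8.4e-04), and Carbon metabolism 41 falls and 16 rises of 93 (median -0.32, camera adjusted p = 0.0268). Both passed after the correction too (camera adjusted p = 0.00975 and 0.0109). The interferon beta gene IFNB1, too low to test and chosen after its values were seen, had 2 and 1 counts in the controls and 7 and 13 in the knockdown.

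Of the 12210 tested genes 6493 were past the threshold. A difference in library size is argued against, since the mean totals differed by -1.59%. Only 23.4% of called genes with a GC value stayed called in the same direction after the GC and length trends were removed, so a GC and length trend between libraries may account for most of the calls. Such a trend was present between libraries of one group as well, with Spearman correlations across genes of GC content and log2 ratio of -0.383 between the controls and -0.437 within the knockdown, against -0.631 to -0.744 between groups. A change of the cells that follows GC content is not separated from it by these 4 libraries and stays open, untested.

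Several of the most changed genes lie side by side. Of 60 genes changed by at least 1.5 on the log2 scale, 7 lay within 100 kb of another, against a median of 0 in 10000 random sets (permutation p = 0.0014). They were ACTN4, ECH1 and HNRNPL, HYOU1 and SLC37A4, and MYO19 and DHRS11. SLC37A4, MYO19 and DHRS11 were named after their values were seen (edgeR adjusted p = 0.00512, 0.047 and 0.0431). Loss or gain of a segment is argued against for the 2 pairs that moved in opposite directions (ECH1 with HNRNPL, HYOU1 with SLC37A4). It stays open for ACTN4 with ECH1 and MYO19 with DHRS11. The 6 other tested genes, pooled over all these windows, had a median of 0.68 with quartiles of 0.01 and 1.15. Each was signed by the direction of the strongly changed genes near it. The pooled value includes windows of the opposite pairs, so it cannot decide the question for the remaining pairs. A further 42 genes differed at least as strongly between the libraries of one group and were not strongly changed themselves. Of these, 9 lay near a strongly changed gene, against a median of 1 in random sets (permutation p = 0.0001, the smallest 10000 sets can give). Some of the 9 lie near each other, whereas the random sets drew genes singly, so this p may be too small. SCRIB for example, chosen after its values were seen, had 317 and 29 counts in the controls. Reads assigned differently between copies of a region may therefore underlie part of these changes, and a response to the knockdown stays open.

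Plasma protein genes of hepatocytes were at or near 0 in libraries given as a hepatocellular carcinoma line, in both groups. Low depth is argued against, since 100 CPM gives 1852 counts in the smallest library. The highest mean of the 23 genes in the deposited FPKM values was 0.065. Those values may rest on the same alignments, annotation or counts, so they cannot decide whether the genes were lost in processing, which stays open. Gene names out of register with the values are argued against by the correlation of -0.735 with the GC content of the transcripts of those names. Albumin and alpha-fetoprotein, which Huh7 is known to make, reached at most 0.106 CPM, so cells other than those the label names are a possible explanation. A subline that had lost these genes would give the same values and was not tested.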
